A study of Arabidopsis thaliana with 4 samples.

How the data were processed

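Total RNA of rosette leaves from TaSK5 transformants OX7 and OX17 and from wild-type plants was profiled on 2-colour Agilent arrays. Per the labels, plants grew at 22 °C with 16 h light and 8 h dark at about 100 µmol per square metre per second, and 500 ng of RNA was labelled by linear amplification. Each transformant had 2 arrays, with its RNA in Cy5 on replicate 1 and in Cy3 on replicate 2. Each array was a different slide with its own scan.

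Per the file headers, the arrays were read with Agilent Feature Extraction 7.5.1, which gave each spot's mean intensity and local background intensity in both channels. The deposited scanner files also hold the program's log10 ratio of Cy5 over Cy3, computed by the program after background subtraction and lowess dye normalisation, per the file headers. The authors deposited a table of processed log2 ratios, and the submitters' processing notes name limma. Its background correction, normalisation and centring are not given in the sources used here. Set against the scanner values of the same array, its columns ran as log2 of Cy5 over Cy3, with r between 0.992 and 0.999 against the loess ratios computed here. Its column medians were -0.00408 and 0.00358 for OX7 replicates 1 and 2, and -0.00543 and 0.00486 for OX17 replicates 1 and 2.

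Intensities were processed with limma 3.58.1 in R 4.3.3. Background was corrected by normexp with an offset of 50. Each array was normalised by loess with 1075 control spots at weight 0, with no step between arrays, and each log2 ratio was turned to TaSK5 over wild type. Spots with outlier flags (60, 144, 145 and 173 on the 4 arrays) were left out and saturated spots kept. A probe was kept where it was well above background in all 4 TaSK5 channels or all 4 wild-type channels. Every locus had 1 probe. Of 21500 loci, 21191 were found in the reference gene table of assembly TAIR10.1, which was used for names and biotypes, and 309 kept the file's name. No genome build is named for the probes, so no coordinates are given. Loess makes the typical ratio of each array 0 at every brightness, so a shift of most transcripts would not be seen, and normexp with its offset shrinks ratios of dim spots.

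Arrays of a transformant were averaged and the 2 means tested against 0 with limma (lmFit and eBayes, 1 residual degree of freedom plus 2.00 prior degrees of freedom, two-sided, Benjamini-Hochberg over 18854 genes, threshold 0.05). The 2 arrays hold 1 RNA pair in both dyes, so dye effects cancel in the mean where neither spot was left out. All 4 arrays had an unflagged spot for 18439 of the 18854 genes. Replicate numbers mark dye orientation and do not pair plants. Lists were tested with camera at a preset correlation of 0.01, adjusted over 24 lists, and again with an estimated correlation and with fry. List members were 413 entries for 407 loci, and 11 entries were not on the array. The symbol matched the table for 396 entries and the locus decided for 17.

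Named genes followed a rule fixed before the data were examined. It took the 12 largest and 12 smallest mean log2 ratios among genes past the threshold, with open places filled by the genes of largest ratio that were at least 2-fold the same way on all 4 arrays. It added up to 4 members of largest ratio per list, all GSK3/Shaggy-like kinases, and the 5 largest and 5 smallest differences between transformants without overlap of arrays. Further list members that passed when adjusted over the list alone were chosen after their values were seen, as was the control with the sign of OX17 turned.

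For the channel comparison, loess ratios and Aquantile-normalised intensities gave a log2 signal per channel, and differences between OX7 and OX17 arrays were taken within each dye orientation and averaged. The gene and list tests were checked on simulated data of 18854 genes with 200 genes changed by known sizes in each of 20 draws. In these data, simulated without correlation between genes, a list of 28 genes shifted by 0.5 was called in 20 of 20 draws and other lists in 0 of 460 tests, which says nothing of false calls among correlated genes. Alternatives were other background corrections, normalisations, filters and fits, leaving out each array, and each transformant alone. Groups of 2 allowed no outlier test and no count of other splits of the samples.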

Results

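Gene expression in rosette leaves of Arabidopsis thaliana plants that over-express a wheat kinase was compared with that in wild-type leaves. TaSK5 is a GSK3/Shaggy-like kinase of wheat, a family whose Arabidopsis members include BIN2, a repressor of brassinosteroid signalling. Its coding sequence was driven by the 35S promoter, a strong viral promoter active in most plant tissues. The plants were 3 weeks old and of the Columbia (Col-0) background, and OX7 and OX17 were independent transformants of the first transgenic generation. RNA of each transformant was hybridised together with wild-type RNA to 2 Agilent 2-colour arrays, with the dyes exchanged between them, so the series held 4 arrays. The 2 arrays of a transformant were repeat hybridisations and counted as 1 replicate, giving n = 2 transformants. The labels do not say whether a wild-type RNA sample came from a single plant or served both transformants. Each array carried 21500 gene probes. Between 86.4% and 95.9% of them were well above background in the TaSK5 channel, and between 88.9% and 96.0% in the wild-type channel. Of these probes, 18854 entered the comparisons, and the number of arrays limits the precision of every value. None of the probes was named for a locus outside Arabidopsis, so the level of the transgene was not analysed here.

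The first question was which genes differed between TaSK5 plants and wild type in both transformants. Of the 46 genes at least 2-fold higher in TaSK5 plants on all 4 arrays, 4 were in the jasmonate and ethylene response list and 4 in the ABA and dehydration response list. VSP2 (AT5G24770), a vegetative storage protein induced by jasmonate, was 7.24-fold higher, with a log2 ratio of 2.86 ± 0.80 (SD, n = 2 transformants). NATA1 (AT2G39030), an ornithine acetyltransferase, followed at 5.86-fold and a log2 ratio of 2.55 ± 0.05. CORI3 (AT4G23600), a coronatine-induced cystine lyase, had a log2 ratio of 2.18 ± 1.12. Among dehydration genes, RD20 (AT2G33380), a caleosin of lipid droplets, stood at 2.34 ± 1.27, the NAC transcription factor RD26 (AT4G27410) at 2.07 ± 0.55 and the related NAC019 (AT1G52890) at 2.15 ± 0.41. PAP1 (AT1G56650), a MYB activator of anthocyanin synthesis, stood at 2.13 ± 1.32. The nitrilase gene NIT2 (AT3G44300) had a log2 ratio of 1.98 ± 0.20 and BGLU18 (AT1G52400), a beta-glucosidase that releases abscisic acid from its glucose ester, one of 1.96 ± 0.06. The FAD-linked oxidoreductase gene AT2G34810 had a log2 ratio of 2.38 ± 1.27. The genes AT5G39520 and AT3G15450, for which the files name no function, had log2 ratios of 2.04 ± 0.31 and 1.95 ± 0.88.

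Fewer genes had lower signal on all 4 arrays. The lowest values belonged to the cysteine proteinase genes AT2G27395, with a log2 ratio of -2.46 ± 1.21, and AT2G27420, with one of -2.26 ± 1.00. The reference table lists AT2G27395 as a transcribed pseudogene, and hybridisation of a transcript to the probes of both was not excluded. A further cysteine protease gene, AT3G49340, had a log2 ratio of -1.58 ± 0.61. AT5G20790 stood at -1.79 ± 0.53, SRG3 (AT3G02040), a glycerophosphodiester phosphodiesterase, at -1.26 ± 0.31, and LHCB4.3 (AT2G40100), a light-harvesting protein of photosystem II, at -1.37 ± 0.02. These 6 were all the genes at least 2-fold lower on each of the 4 arrays, against 46 at least 2-fold higher. No gene was at least 2-fold towards the same dye on all 4 arrays, and 11 were at least 2-fold in opposite directions in the 2 transformants. With median centring in place of loess, the counts were 26 higher and 11 lower.

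None of these single-gene differences passed the test. With limma on the 2 transformant means, 0 genes were higher and 0 lower at a Benjamini-Hochberg adjusted p under 0.05. The smallest adjusted p was 0.846, and 825 genes had an unadjusted p under 0.05, where 942.7 would come with no effect. With the sign of the OX17 ratios turned, a control chosen after seeing the data, 390 genes did. Counting the 4 arrays as independent, which takes repeat hybridisations for plants, gave 66 higher and 13 lower. In data simulated with the spread that limma estimated, this test called 25.8% of genes made 8-fold different, 0.373% of those made 4-fold different and 0% of those made 2-fold different. Single-gene values are therefore given as measured differences.

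**Figure D1:**
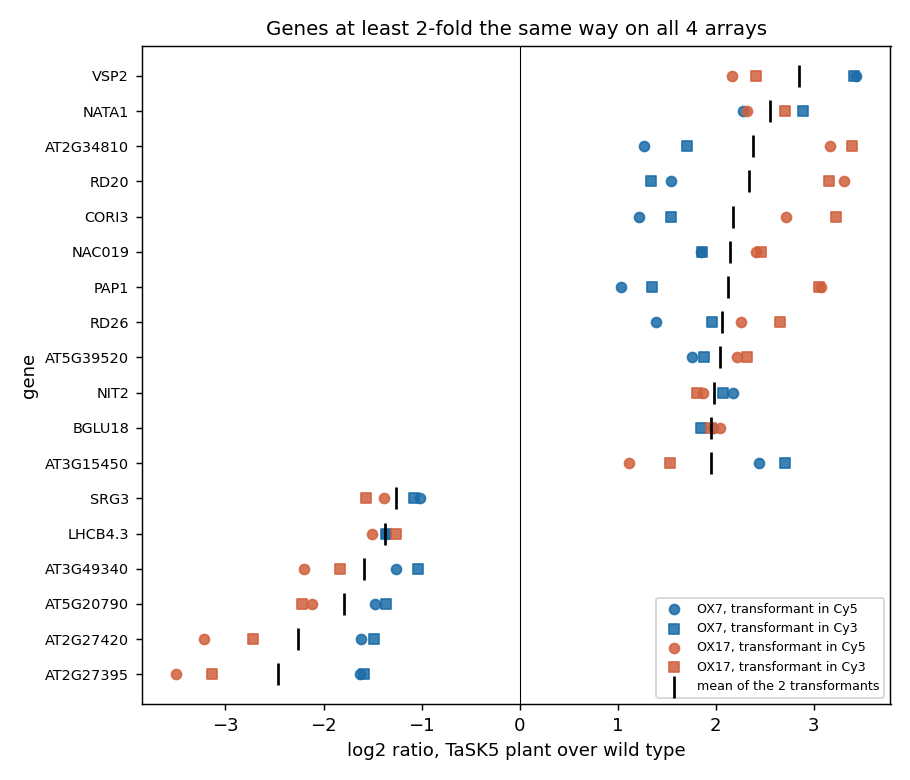
Log2 ratio of TaSK5 plant over wild type (x axis) for the 12 genes of highest and the 6 of lowest mean ratio among genes at least 2-fold the same way on all 4 arrays (y axis). Circles and squares are single arrays of the 2 dye orientations, blue for OX7 and orange for OX17, and black bars are the means of the 2 transformants, from 2.86 for VSP2 to -2.46 for AT2G27395.

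Groups of genes were compared through 25 lists fixed before the data were examined, of which 24 had measured members. With limma's camera test and a preset correlation of 0.01, 6 lists stood higher and 4 lower than the other genes at an adjusted p under 0.05. With an estimated correlation, none did, and each of these 10 lists had an adjusted p = 0.752. That option refers each list to 1 residual degree of freedom, so hardly any list could pass. The ABA and dehydration response list had an estimated correlation of 0.0246, and its unadjusted camera p still rose from 9.19e-11 to 0.112. The other called lists had estimated correlations from -0.0909 for sugar starvation to 1 for cytokinin response, with 0.492 for jasmonate and 0.810 for salicylic acid. The loss of calls therefore neither shows nor excludes that correlation between genes made them. With the preset correlation, camera sets a list against the other genes, so its p does not measure the spread between plants. The fry test asks another question, whether a list differs from no change, and 0 lists passed it, with adjusted p from 0.482 to 0.717 for these 10. For lists too, the sign of the OX17 ratios was turned as a control chosen after seeing the data. This removes a shared effect from the mean only where it is of equal size in both transformants. With the sign turned, 9 of 24 lists passed camera, 4 of them among the 10: the jasmonate, salicylic acid, brassinosteroid growth and cytokinin lists. These 4 had medians of the same sign in both transformants, larger in OX17. In OX7 the salicylic acid median was -0.096 on replicate 1 and 0.086 on replicate 2. The brassinosteroid growth and cytokinin medians in OX7 lay at percentiles 8.62 and 5.21 of intensity-matched random lists. The control therefore cannot tell false calls from a shared effect of unequal size or from a difference in OX17 alone.

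The jasmonate and ethylene response list had the largest median in the mean of both transformants, though not in OX7, where 6 lists had a higher one. Its 28 measured genes had a median log2 ratio of 0.81, and 14 were higher and 0 lower on all 4 arrays (camera adjusted p = 7.80e-14; adjusted p = 0.752 with an estimated correlation). The median was 0.27 in OX7 and 1.15 in OX17. LOX2 (AT3G45140), the chloroplast lipoxygenase of jasmonate synthesis, had a log2 ratio of 1.69 ± 0.71 with 1 saturated spot, and JAZ1 (AT1G19180), a repressor that jasmonate induces, one of 1.34 ± 0.18. Over all genes 0 members passed, and 7 passed when adjusted over the list alone. They were VSP2, LOX2, LOX3 (AT1G17420), JAZ1, JAZ5 (AT1G17380), TIFY10B (AT1G74950) and TIFY7 (AT1G70700), of which LOX3, JAZ5, TIFY10B and TIFY7 were chosen after their values were seen.

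The ABA and dehydration response list, genes that abscisic acid, drought, salt or cold induce, had a median log2 ratio of 0.60 over 29 genes. In it, 16 genes were higher and 1 was lower on all 4 arrays (camera adjusted p = 1.10e-09; adjusted p = 0.752 with an estimated correlation). Its medians were 0.43 in OX7 and 0.75 in OX17. Besides RD20 and RD26, GolS1 (AT2G47180), a galactinol synthase, had a log2 ratio of 1.63 ± 0.25 and KIN2 (AT5G15970), a cold-induced protein, one of 1.35 ± 0.40. GolS1 was the only member that passed when adjusted over the list alone, and 0 passed over all genes. The ABA signalling list had a median of 0.47 over 16 genes, with 10 higher and 0 lower on all 4 arrays (camera adjusted p = 1.27e-06; adjusted p = 0.752 with an estimated correlation), and medians of 0.40 in OX7 and 0.64 in OX17. Among its genes, the protein phosphatase gene HAI1 (AT5G59220) stood at 1.61 ± 0.95 and PP2CA (AT3G11410), also a phosphatase of abscisic acid signalling, at 0.85 ± 0.07 on 3 arrays. The OX7 value of PP2CA came from replicate 1 alone, so a dye effect does not cancel in it.

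The leaf senescence list had a median log2 ratio of 0.76 over 13 genes, with 9 higher and 0 lower on all 4 arrays (camera adjusted p = 2.68e-07; adjusted p = 0.752 with an estimated correlation). Its median was 0.32 in OX7 and 0.98 in OX17. SAG13 (AT2G29350) had a log2 ratio of 2.03 ± 1.21 on 3 arrays, the NAC factor NAP (AT1G69490) 1.45 ± 1.47 and SEN1 (AT4G35770) 1.07 ± 0.77. The OX17 value of SAG13 came from replicate 1 alone, so a dye effect does not cancel in it. The sugar starvation list had a median of 0.45 over 11 genes, with 7 higher and 0 lower on all 4 arrays (camera adjusted p = 0.000422; adjusted p = 0.752 with an estimated correlation), and medians of 0.30 in OX7 and 0.41 in OX17. The trehalose phosphate synthase family genes TPS11 (AT2G18700) and TPS8 (AT1G70290) had log2 ratios of 1.67 ± 0.95 and 1.54 ± 0.56. The salicylic acid defence list had a median of 0.48 over 21 genes, with 6 higher and 1 lower on all 4 arrays (camera adjusted p = 1.05e-05; adjusted p = 0.752 with an estimated correlation). Its median was 0.08 in OX7, with -0.096 on replicate 1 and 0.086 on replicate 2, and 0.84 in OX17. PAD3 (AT3G26830), of camalexin synthesis, stood at 1.19 ± 1.57 and WRKY53 (AT4G23810) at 1.07 ± 0.48. In these 3 lists 0 members passed over all genes and 0 when adjusted over the list alone.

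The 4 lists that passed the test with lower values were brassinosteroid-induced growth, cytokinin response, circadian clock and cell division. The brassinosteroid-induced growth genes had a median log2 ratio of -0.37 over 16 genes, with 1 higher and 4 lower on all 4 arrays (camera adjusted p = 0.00165; adjusted p = 0.752 with an estimated correlation). Their median was -0.07 in OX7, at percentile 8.62 of intensity-matched random lists, and -0.51 in OX17. The expansin genes EXPA8 (AT2G40610) and EXPA1 (AT1G69530), which loosen cell walls, had log2 ratios of -1.36 ± 1.75 and -1.26 ± 2.03. These low means came from OX17, with -0.12 in OX7 and -2.60 in OX17 for EXPA8 and 0.18 and -2.70 for EXPA1. The cytokinin response list, type-A response regulators, had a median of -0.39 over 8 genes, with 0 higher and 3 lower on all 4 arrays (camera adjusted p = 0.00269; adjusted p = 0.752 with an estimated correlation). Its median was -0.10 in OX7, at percentile 5.21 of intensity-matched random lists, and -0.57 in OX17. ARR15 (AT1G74890) stood at -0.45 ± 0.16. The circadian clock list had a median of -0.15 over 22 genes (camera adjusted p = 0.0115; adjusted p = 0.752 with an estimated correlation), with PRR9 (AT2G46790) at -0.53 ± 0.36. On all 4 arrays 2 clock genes were higher and 5 lower, and the list's median was -0.099 in OX7 and -0.23 in OX17. Without OX17 replicate 2 the list's call ended, at a median of -0.0747. The cell division list had a median of -0.11 over 12 genes (camera adjusted p = 0.0217; adjusted p = 0.752 with an estimated correlation) and passed under 12 of the 21 alternatives. Its median in OX7 was -0.08, at percentile 18.64 of intensity-matched random lists. Its call ended without OX7 replicate 2, at a median of -0.0769, and without OX17 replicate 2, at one of -0.0673. With median centring its median turned to 0.02. In these 4 lists 0 members passed over all genes and 0 when adjusted over the list alone.

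**Figure D2:**
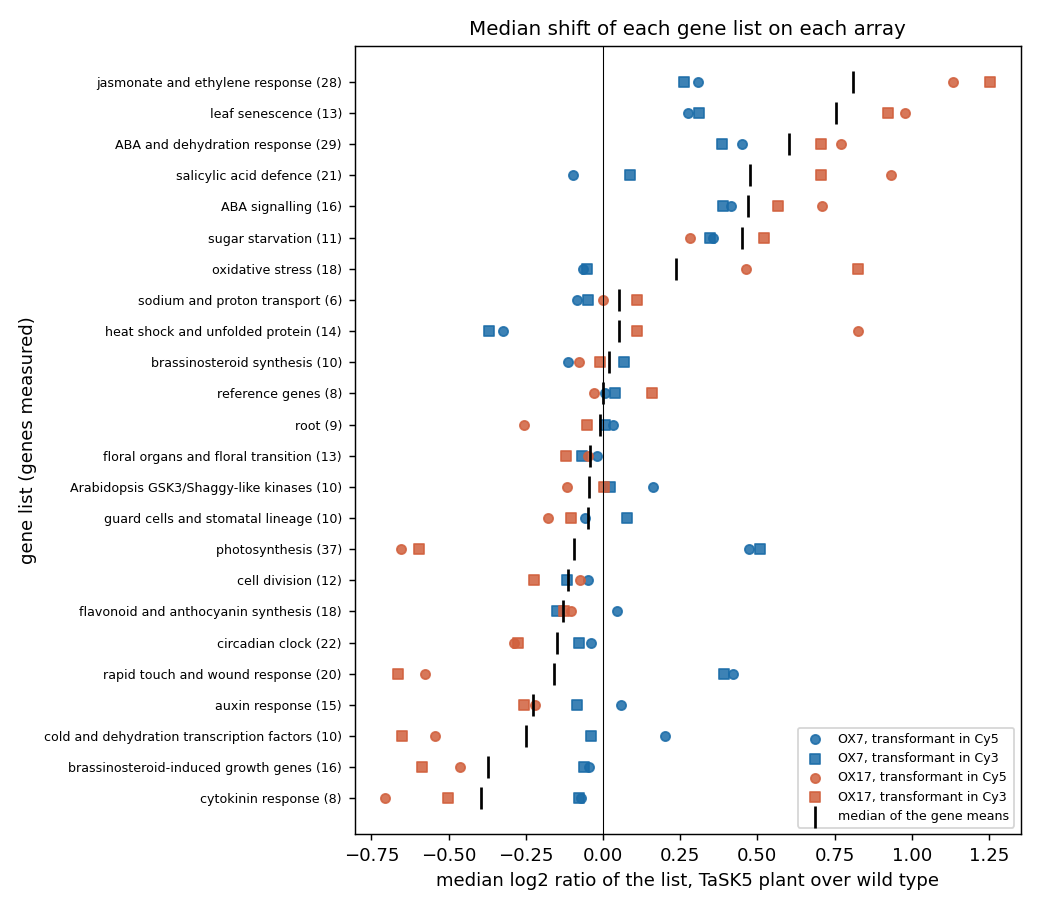
Median log2 ratio of TaSK5 plant over wild type (x axis) of each gene list, with the number of measured genes in brackets (y axis). Circles and squares are the medians on single arrays of the 2 dye orientations, blue for OX7 and orange for OX17, and black bars are medians of the gene means; the jasmonate and ethylene response list has the highest, at 0.81, and the photosynthesis list lies on opposite sides of 0 in the 2 transformants.

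The other lists did not pass the test. In the flavonoid and anthocyanin synthesis list, with a median of -0.13 over 18 genes (camera adjusted p = 0.232), 4 genes were higher and 7 lower on all 4 arrays. PAP1 was among the higher genes and the synthesis gene C4H (AT2G30490), chosen after its values were seen, stood at 0.38. TT4 (AT5G13930), chalcone synthase, had a log2 ratio of -1.25 ± 0.46 and F3H (AT3G51240), flavanone 3-hydroxylase, one of -0.93 ± 0.35. The oxidative stress list had a median of 0.24 over 18 genes (camera adjusted p = 0.0608) and passed under 10 of the 21 alternatives. Its catalase gene CAT3 (AT1G20620) stood at 1.00 ± 0.29, and the glutathione transferase gene GSTU4 (AT2G29460) at 1.81 ± 1.79. Medians were -0.23 for the auxin response (adjusted p = 0.322), -0.25 for cold and dehydration transcription factors (adjusted p = 0.189), 0.02 for brassinosteroid synthesis (adjusted p = 0.920) and 0.05 for sodium and proton transport (adjusted p = 0.935), where the mean was -0.05. Markers of other tissues and cells had medians of -0.04 for floral organs (adjusted p = 0.337), -0.05 for guard cells (adjusted p = 0.546) and -0.01 for root (adjusted p = 0.935), where the mean was 0.13. In the root list, PYK10 (AT3G09260), a beta-glucosidase of endoplasmic reticulum bodies, was higher, at 1.88 ± 0.72. The 8 genes often used as references had a median of 0.00 (adjusted p = 0.546). UBQ10 (AT4G05320), a polyubiquitin gene among them, passed the limma test when adjusted over this list alone (adjusted p = 0.0295). It had 2 saturated spots and OX17 arrays at 0.39 and 1.71, so its ratio was not reliable. The list of organelle-encoded transcripts had no probe among those analysed here.

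The second question was whether the plant's own GSK3/Shaggy-like kinases differed. The 10 measured members had a median log2 ratio of -0.05 and a mean of 0.12 (camera adjusted p = 0.728), and 0 passed, over all genes or adjusted over the list alone. SK32 (AT4G00720) was higher on all 4 arrays, at 1.18 ± 0.49, with 1.53 in OX7 and 0.84 in OX17. No probe or transgene sequence was available, so signal from the TaSK5 transcript at this probe was not excluded. The kinase gene AT5G26751 was also higher on all 4, at 0.32 ± 0.24. BIN2 (AT4G18710) had a log2 ratio of 0.00 ± 0.23, and its sign differed between alternatives. SK13 (AT5G14640) stood at 0.20 ± 0.61 and the other 6 between -0.11 and -0.04, namely AT3G61160, GSK1 (AT1G06390), ATSK12 (AT3G05840), SKdZeta (AT2G30980), SK41 (AT1G09840) and SK42 (AT1G57870).

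The third question was how far the 2 transformants resembled each other. Across genes, which are not independent replicates, the mean log2 ratios of OX7 and OX17 correlated with a Pearson r of 0.18 and a Spearman rho of 0.15. The Pearson r was 0.0843 without OX17 replicate 2 and 0.258 without OX17 replicate 1. The dye-swapped arrays of 1 transformant correlated with r of 0.58 for OX7 and 0.76 for OX17. Ratios spread more widely in OX17, with an SD across genes of 0.50 against 0.24 in OX7. On both arrays, 92 genes were at least 2-fold higher and 18 lower in OX7, and 489 higher and 380 lower in OX17. Unrelated lists of these sizes would share 2.44 higher and 0.371 lower genes, where 46 and 6 were shared. The same rule gives 2.37 genes in opposite directions, where 11 were found, so it sets the number expected by chance too low. The simulated data had no array noise or correlation between genes. In them, 2049 unchanged genes over 20 draws were at least 2-fold the same way, which is more per draw than were shared here. Such genes fall in opposite directions as often, against 11 here, so the simulated number is too high to serve as the chance number. The numbers expected of unrelated lists hold only if the 2 array pairs shared no wild-type RNA. The 2 transformants differed by at least 2-fold without overlap of their arrays in 1086 genes, in 1704 with Agilent processed log ratios and in 726 with scaling between arrays. This number holds differences between the plants and between the wild-type channels. The rule sets them against technical spread alone, since each transformant was a single plant. Without the 2-fold rule, separating 2 values from 2 others by chance has a share of 1 in 3.

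**Figure D3:**
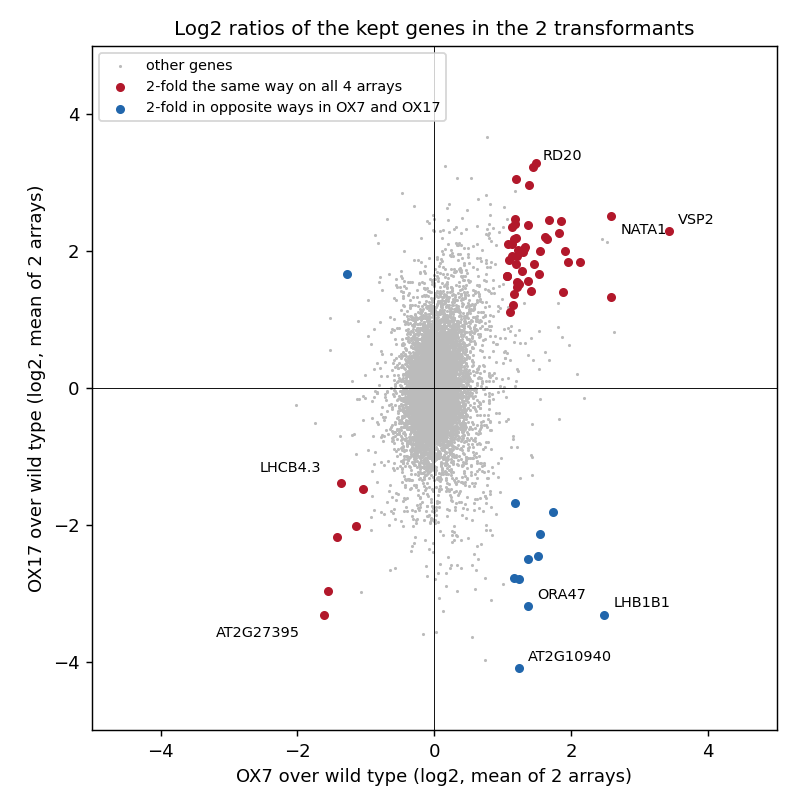
Mean log2 ratio over wild type of each kept gene in OX7 (x axis) and OX17 (y axis), each the mean of 2 dye-swapped arrays. The 52 genes at least 2-fold the same way on all 4 arrays are red, the 11 genes at least 2-fold in opposite ways are blue, and the spread is wider along the OX17 axis, with an SD of 0.50 against 0.24.

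The photosynthesis, touch and heat shock lists had median ratios over wild type of opposite sign on the OX7 and OX17 arrays, though not every member did. On all 4 arrays, 3 photosynthesis genes were lower, 2 touch genes were higher and 2 lower, and 1 heat shock gene was lower. The 37 photosynthesis genes had a median log2 ratio of 0.45 in OX7 and -0.64 in OX17, which left a median of -0.09 in the mean of both (camera adjusted p = 0.322). With median centring that median was -0.38 and the list passed (adjusted p = 3.24e-06), it also passed with the deposited table (0.0426) and without OX17 replicate 2 (0.0388), and with scaling between arrays the median turned to 0.07. The light-harvesting gene LHB1B1 (AT2G34430) had log2 ratios of 2.48 in OX7 and -3.31 in OX17, and AT2G10940 had 1.24 and -4.10. DELTA-TIP (AT3G16240), a vacuolar water channel, had 0.74 and -3.97, and AT5G44020, a gene like those of vegetative storage proteins, had 0.55 and -3.64. ORA47 (AT1G74930), an ERF transcription factor of jasmonate synthesis, had 1.37 and -3.18. The 20 genes of the rapid touch and wound response had medians of 0.39 in OX7 and -0.54 in OX17, and their median over both was -0.16 (camera adjusted p = 0.546), or 0.01 with scaling between arrays. The 14 heat shock genes had medians of -0.32 and 0.44 (camera adjusted p = 0.728). HSP70 (AT3G12580) had log2 ratios of -0.69 and 2.47, HSP90.1 (AT5G52640) -0.87 and 2.24, and the small heat shock gene AT1G07400 -1.28 and 1.67. GolS2 (AT1G56600) had -0.29 and 2.67, and ERF53 (AT2G20880), a dehydration-induced factor, 0.15 and 3.24. With 1 plant each, these differences were not tested.

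The channels were also compared one at a time between the array pairs. In the wild-type channels, the touch and wound genes had a median difference of -1.58 log2 units (OX7 arrays minus OX17 arrays), and in the TaSK5 channels one of -0.58. Both channels were thus lower on the OX7 arrays, the wild-type channels by more. The TaSK5 difference alone would lower the ratios of OX7 against those of OX17, where the list's ratios were higher. The opposite ratios of this list therefore lay in the wild-type channels. For cold and dehydration transcription factors the wild-type channels differed by a median of -1.02 and the TaSK5 channels by -0.01. For photosynthesis genes the order was the other way, with -0.21 between wild-type channels and 0.80 between TaSK5 channels. The wild-type channels of the 2 pairs differed at least 2-fold in both dye orientations in 146 genes that were higher and 227 that were lower on the OX7 arrays. The TaSK5 channels did so in 356 and 378 genes.

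**Figure D4:**
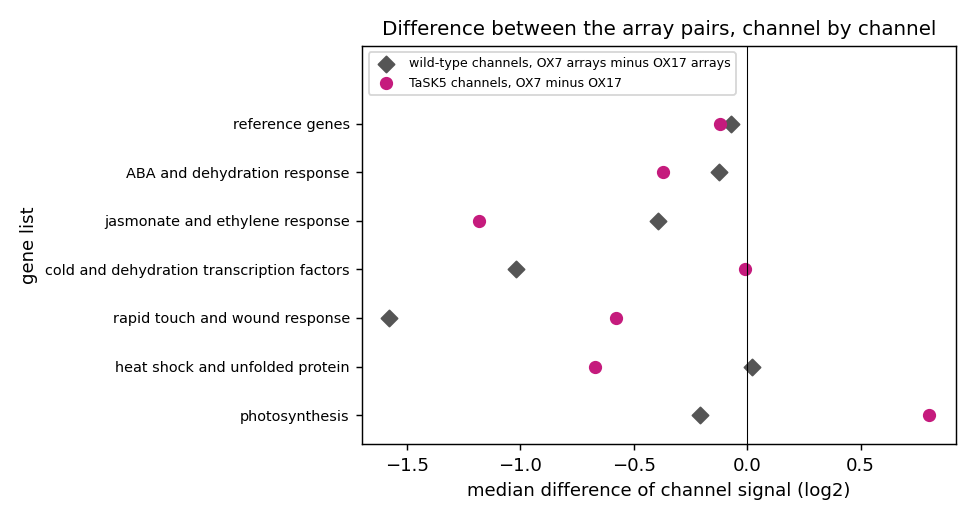
Median difference of normalised channel signal (log2, x axis) between OX7 arrays and OX17 arrays for 7 gene lists (y axis), for wild-type channels (grey diamonds) and TaSK5 channels (pink circles). Touch and wound genes differ most between wild-type channels, by -1.58, and photosynthesis genes differ by 0.80 between TaSK5 channels.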

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

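The tests on photosynthesis genes below were set before their results were seen, and the control spots were examined only after the data were seen. Differences here are between log2 ratios over wild type on the OX7 and OX17 arrays, so they can lie in either channel, and they were not tested, because each transformant was a single plant.

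In 6 of 24 lists, both OX7 arrays had a median on the other side of 0 from both OX17 arrays. The median difference, OX7 minus OX17 in log2 units, was 1.01 for photosynthesis, 1.32 for the rapid touch and wound response and -0.999 for heat shock and unfolded protein. It was -0.41 for oxidative stress, 0.28 for root and -0.14 for sodium and proton transport.

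For photosynthesis genes, 3 technical accounts were weighed. The loess fit or saturation of bright spots would remove most of the difference when changed. Median centring enlarged it to 1.15, and leaving out the 21 members with a saturated spot left 0.79, a loss of at most 22.3%, so this is not the whole account. Random lists of equal brightness did not shift this way either, since the list lay at percentile 100 in OX7 and 0.01 in OX17. A difference between the wild-type channels made up 20.7% of it, with a range of 2.32% to 43.0% over resampled members, so its share stays open. A difference between the transformants themselves may remain and, with 1 plant each, was untested.

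Among 122 genes chosen by the naming rule, 28 had opposite signs in OX7 and OX17 on both arrays. The difference in log2 ratio, OX7 minus OX17, was 5.79 for LHB1B1, 5.33 for AT2G10940, 4.70 for DELTA-TIP, 4.55 for ORA47 and 4.18 for AT5G44020. It was -3.16 for HSP70, -3.10 for HSP90.1, -2.96 for GolS2, -2.95 for AT1G07400, -1.98 for HSFA2 (AT2G26150) and -1.94 for BIP3 (AT1G09080). Stress transcription factors had 3.02 for CBF2 (AT4G25470), 2.88 for STZ (AT1G27730), 2.47 for RRTF1 (AT4G34410) and 2.35 for ERF104 (AT5G61600), and the calmodulin-like CML38 (AT1G76650) had 1.69. For CBF2 and STZ the difference lay in the wild-type channels, which differed by -3.08 and -2.98 (OX7 arrays minus OX17 arrays), while the TaSK5 channels differed by -0.06 and -0.10. The wild-type and TaSK5 channels differed by -3.14 and -0.68 for RRTF1, -2.70 and -1.01 for CML38 and -1.64 and 0.71 for ERF104. For HSP90.1 the difference was split, at 1.57 and -1.53, as it was for HSP70, and for EXPA1 (-0.07 and 2.81) and DWF1 (-0.60 and 1.71) it lay mostly in the TaSK5 channels. Growth-related genes had 2.87 for EXPA1, 2.31 for DWF1 (AT3G19820), 1.63 for IAA14 (AT4G14550) and 0.98 for ARR9 (AT3G57040). The Rubisco small subunit gene RBCS1B (AT5G38430), with 4 saturated spots, had 2.14, COL2 (AT3G02380) 1.95, GSTF6 (AT1G02930) -2.55 and the actin gene ACT8 (AT1G49240) 0.69. Among kinases, the difference was -0.87 for SK13, 0.52 for GSK1, 0.38 for AT3G61160 and 0.28 for SKdZeta.

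A signal also appeared in control spots, which entered no comparison. A positive control probe with no gene name, spotted 49 times, had a mean log2 ratio of TaSK5 over wild type of 1.09 across the 4 arrays. Its array medians were 0.72, 0.58, 1.69 and 1.38. Another positive control probe, also spotted 49 times, had array medians of 0.63, 0.70, -0.10 and -0.36.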

How the results depend on the processing

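The comparison of separate channels was chosen after seeing the data, and all other alternatives before. The cause of a change was not tested, apart from alternatives that use fewer arrays. The 0 genes past the threshold stayed at 0 in both directions under all alternatives except 2. With no dye term and transformant as a random block, 43 were higher and 5 lower. With 4 arrays as independent, 66 were higher and 13 lower. With the dye term as a replicate block, 0 were higher and 0 lower, with 1499 genes at an unadjusted p under 0.05, and 10 lists passed: cell division no longer did (adjusted p = 0.124) and oxidative stress did (0.0227). Genes at least 2-fold higher on all 4 arrays numbered 70 and lower 10 with Agilent processed log ratios, against 46 and 6, and 26 and 11 with median centring. With scaling between arrays 10 were lower. OX7 alone gave 92 and 18, and OX17 alone 489 and 380. With Agilent processed ratios 1704 genes differed between transformants, against 1086. The correlation of OX7 and OX17 ranged from 0.0843 to 0.258 with each array left out. The number of lists past the threshold was 0 with an estimated correlation, which refers each list to 1 residual degree of freedom. It was 0 with fry, where the cause was not tested, and 9 to 11 elsewhere.

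Of the lists that turned sign in alternatives with both transformants, touch and wound (-0.16) and cell division (-0.11, called) had the medians furthest from 0. With median centring, medians were 0.0169 for cell division, 0.0162 for floral organs, 0.0969 for root and -0.110 for reference genes. With scaling they were 0.0716 for photosynthesis, 0.0142 for touch and wound, 0.0204 for root and -0.00689 for brassinosteroid synthesis. Reference genes stood at -0.00643 with no background correction and -0.00586 with the deposited table, and root at 0.00308 with an offset of 0. With each array left out, medians ranged from -0.0275 to 0.0957 for reference genes, -0.104 to 0.0401 for brassinosteroid synthesis and -0.0877 to 0.00443 for the kinases. Photosynthesis passed camera with the deposited table (adjusted p = 0.0426), median centring (3.24e-06) and without OX17 replicate 2 (0.0388). Of the 10 called lists, 8 passed in every alternative with the preset correlation.

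Of 2674 values of named genes under alternatives, 30 passed the threshold, 14 were counted as turned in sign and 2630 as neither. The 14 came from alternatives with both transformants, and turns of sign in OX7 alone or OX17 alone were not counted. The 28 named genes with opposite signs in OX7 and OX17 each turned sign in OX7 alone or OX17 alone. LHB1B1, for example, had a log2 ratio of -0.415 in the mean of both and 2.48 in OX7. BIN2 (AT4G18710) was -0.0005 with Agilent ratios, -0.0049 with the deposited table and -0.105 with median centring. MCM2 (AT1G44900) was 0.0265 with median centring. With scaling, LHB1B1 (AT2G34430) was 0.475, AT1G07400 -0.247, DWF1 (AT3G19820) 0.0006 and ACT8 (AT1G49240) 0.0152. With each array left out, BIN2 (AT4G18710) ranged from -0.0904 to 0.0983, SK41 (AT1G09840) from -0.172 to 0.0749, SKdZeta (AT2G30980) from -0.196 to 0.0111, SK42 (AT1G57870) from -0.129 to 0.0404 and PRP3 (AT3G62680) from -0.0542 to 0.208.

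Quantile normalisation of average intensities leaves ratios as they are, and the rule for several probes per locus moves nothing with 1 probe per locus. Slide or scan could not be fitted as a block, since each array had its own. Signal over background limits dim genes, and 18854 of 21500 probes passed the filter.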

Other observations

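The lists in this part were chosen after the data were seen, as were the tests on dye, chance overlap and wild-type RNA; the phosphate test was set before its genes were looked up. Genes named here outside the naming rule were chosen after their values were seen.

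Genes of endoplasmic reticulum bodies, which store defensive beta-glucosidases, and of jacalin-related lectins had mostly higher values. Of 15 measured genes, 12 were higher and 0 lower on all 4 arrays (camera p = 0.310 with an estimated correlation), with medians of 0.19 in OX7 and 1.02 in OX17. BGLU18 and TSA1 (AT1G52410) had log2 ratios of 1.96 ± 0.06 and 1.60 ± 0.10 (SD, n = 2 transformants), JAL23 (AT2G39330) 1.91 ± 0.42 and JR1 (AT3G16470) 1.65 ± 0.49. These values include 5 genes that prompted the list. Of the 10 genes whose values had not been seen, 7 were higher and 0 lower on all 4 arrays, with medians of 0.14 in OX7 and 0.51 in OX17. Their median in the mean of both was 0.35, at percentile 99.24 of intensity-matched random lists in OX7 and 100 in OX17, and camera gave them p = 4.99e-05 with the preset correlation and p = 0.408 with an estimated correlation. NAI1 (AT2G22770), the transcription factor of these bodies, stood at 0.69 ± 0.93 and the body protein gene NAI2 (AT3G15950) at 0.35 ± 0.15.

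A hypothesis drawn from SRG3 and AT5G20790 was that the phosphate starvation response may be lower in TaSK5 plants. Of the other 18 genes listed for it, 17 were measured, with a median log2 ratio of -0.20. Array medians were -0.23, -0.39, -0.22 and -0.20, and the median lay at percentile 0 of 10000 intensity-matched random lists. SPX1 (AT5G20150), a phosphate sensor, stood at -1.50 ± 0.82, SQD1 (AT4G33030) and SQD2 (AT5G01220), of sulfolipid synthesis, at -0.59 ± 0.21 and -0.44 ± 0.04. In all, 7 genes were lower and 1 was higher on all 4 arrays, the phosphate starvation gene PHT1;4 (AT2G38940) at 0.28 ± 0.22. PLDP2 (AT3G05630), RNS1 (AT2G02990) and NPC4 (AT3G03530) also had mean log2 ratios above 0, at 0.22, 0.21 and 0.09. Camera's p was 0.000323 with the preset correlation and 0.161 with an estimated correlation. The list's median went the way of the hypothesis in these 2 plants, though not every member did.

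The 52 genes at least 2-fold the same way on all 4 arrays were weighed against technical accounts. A dye effect turns sign between the swapped arrays of a transformant, so by design it cannot alone put a gene the same way on all 4. The 0 genes at least 2-fold towards a dye on all 4 arrays therefore decide nothing here, and smaller dye effects were not excluded. Chance overlap of unrelated lists would give 2.81 genes if genes were independent. The same rule gives 2.37 genes in opposite directions, where 11 were found, so it sets the number too low. Data were also simulated without array noise or correlation between genes. There, 2049 unchanged genes over 20 draws were at least 2-fold the same way, more per draw than the 52 found. Unchanged genes fall in opposite directions as often there, against 11 found here, so the simulated number is too high to serve as the chance number. Neither number allows for genes that change together in a plant, so chance was not excluded. If 1 wild-type RNA had been on all arrays, wild-type channels of the pairs would differ by noise alone. Their difference correlated between dye orientations with r of 0.64, which was 0.399 above the higher correlation of wild-type with TaSK5 differences, so a single wild-type RNA is unlikely. Open explanations include chance agreement of 2 plants and TaSK5 itself. They also include any difference in how transformed and wild-type plants were raised or handled, which goes with genotype on every array.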
